A study of Homo sapiens with 8 samples.

How the data were processed

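The series holds ChIP-seq of POLR3A, the largest subunit of RNA polymerase III, in the human breast cancer line MDA-MB-231 and in its highly metastatic derivative MDA-LM2. Each line has 2 POLR3A ChIP libraries, and 4 input libraries belong to the series as well. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 minutes, chromatin was sheared to fragments of 200 to 1000 bp, and reads were 50 nt long. Only the 4 ChIP lists were analysed, and no file of an input library was used here. Nothing in the labels says whether replicates came from separate cultures, so the spread between replicates may be technical.

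The authors deposited 1 list of regions per ChIP library, so regions were called per library and not on pooled replicates. The submitters' processing notes name the hg19 build, Bowtie2 2.2, bedtools and DESeq, with no role or order. The region caller, its threshold and the way input reads were used are not given in the sources used here. The lists have 11 columns and no header, and the meaning of each column was read from its values. The authors' deposited strength score is a positive number per region whose definition is not given in the sources used here. A further deposited score behaves like the logarithm of a p-value of unknown base, and every finite value of it is below -10. The deposited signal is the height of the pile-up at the highest position of a region, in whole numbers, with no correction for depth that the values show. A percent column, as the authors deposited it, places the highest position within the region. Scores and heights were used only to rank or describe regions within 1 list. Read totals are not given in the sources used here, so the depth of each library is unknown, and list lengths cannot be corrected for depth or for the yield of the ChIP.

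Region positions are hg19 positions as the files give them, and whether starts count from 0 or 1 is not given in the sources used here. No hg19 annotation was used, so no region was assigned to a gene. The RefSeq gene table of GRCh38.p14 served only for names, for the chromosome of each gene and for which genes neighbour each other. No coordinate was converted between builds.

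Regions of different lists were called shared when they overlapped by at least 1 bp. For each of the 6 pairs of libraries, the regions of the shorter list were placed 1000 times at random on their own chromosome, within the span of all listed regions, and the one-sided permutation p was adjusted by Benjamini-Hochberg over the 6 pairs. Overlapping regions of the 4 lists were also merged, and merged regions were counted by the libraries that held them. Merging chained overlaps, so libraries that hold the same merged region need not overlap each other directly. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Fisher's exact tests and permutation tests on regions compare lists with each other, and regions are not independent replicates of a line. The counts per line were compared by an exact two-sided permutation test, in which 2 libraries against 2 allow no p below 0.333.

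The regions named in the text follow a rule that was set beforehand. It took up to 15 regions held by at least 3 of the 4 libraries, ordered by the number of libraries and then by mean percentile of the strength score. It also took up to 10 regions per line held by both of its libraries and by neither of the other line, and the 5 strongest regions of each library. Clusters, the chromosome 1 array and single regions named outside this rule were chosen after their values were seen.

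The following were chosen after the data were examined. Regions were split into those within 2 Mb of a centromere or heterochromatin gap of hg19 and those farther away, a distance picked after the distances of all regions had been tabulated. The gap bounds were entered by hand from general knowledge of hg19, rounded to 0.1 Mb, and do not come from a source used here. The end of the gap on the long arm of chromosome Y was moved after 2 regions of MDA-MB-231 replicate 1 had been found inside the first entry. Also chosen afterwards were the comparisons of regions near and away from gaps, the placement of regions 5 to 50 kb from their own position, the clusters, the chromosome 1 array (the 0.1 Mb bin with the most regions away from the gaps over the 4 lists), the strength of shared regions and the correlations with tRNA genes per chromosome. Clusters were runs of 1 Mb windows with at least 10 regions in all, counted over the 4 lists away from the gaps. For each of 9 clusters, the share of regions of MDA-MB-231 replicate 1 found in each MDA-LM2 list was compared with its other regions away from the gaps, by Fisher's exact test with Benjamini-Hochberg adjustment over 18 tests. The 8 correlations used 100000 permutations, and tests of medians within a list used 10000. For the array and the chromosome 6 cluster, regions were also permuted 10000 times within 5 classes of strength of the list they came from.

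The alternatives fixed before the data were examined were a reciprocal overlap of 50%, a distance of 500 bp, the strongest 50% of each list, the strongest 18 regions of each list and leaving out each library. Alternatives added after the data were examined were gap distances of 1 and 5 Mb, regions away from gaps only, placements 5 to 50 kb away, the number of merged regions with each library left out, and, for the array regions, a distance of 500 bp and permutation within classes of strength. The difference between the lines in regions per library was also computed with the replicate number as a block, by an exact sign-flip test over 2 pairs, with crossed numbers, with each library left out and with the strongest 50% of each list. Planned work that needs an hg19 annotation was not run: RNA polymerase III genes by class, tRNA genes by anticodon, the shares of regions at RNA polymerase III genes and at promoters, and the prepared gene lists. Differential occupancy was not tested, because the lists used here hold no values for a common set of features. Random placement was tested on simulated data. Planted regions were slightly moved copies of listed regions, so their recovery was certain. Lists with none planted were drawn by the same random placement, without the clustering of the real regions. These runs therefore check the code only. With 8 planted overlaps, all 8 were recovered in 20 of 20 runs for MDA-MB-231 replicate 2 in MDA-MB-231 replicate 1, a list of 18 regions. With none planted, 1 of 200 runs of that comparison had p at most 0.05. For MDA-LM2 replicate 1 in MDA-LM2 replicate 2, a list of 86 regions, all 8 were recovered in 20 of 20 runs, and 5 of 200 runs with none planted had p at most 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.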

Results

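RNA polymerase III, which transcribes tRNA, 5S rRNA and other short RNAs, was mapped by ChIP-seq of its subunit POLR3A in MDA-MB-231 breast cancer cells and in MDA-LM2, a derivative of that line with high metastatic capacity. The comparison of the lines asks where in the genome occupancy by the polymerase differs between the less and the more metastatic cells. Each line had 2 replicate ChIP libraries, and each library had its own list of enriched hg19 regions. MDA-MB-231 replicates 1 and 2 listed 646 and 18 regions, and MDA-LM2 replicates 1 and 2 listed 86 and 472. The regions covered 265 kb, 3.62 kb, 17.4 kb and 165 kb of the genome in that order. Their median widths were 279, 171.5, 163.5 and 219.5 bp. The depth of the libraries is unknown.

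The lines did not differ in the number of listed regions beyond the spread between replicates. MDA-MB-231 had 332 ± 444 regions (SD, n = 2) and MDA-LM2 had 279 ± 273 (SD, n = 2), and the exact two-sided permutation p was 1, where the smallest possible value is 0.333. The difference of the means, MDA-LM2 minus MDA-MB-231, was -53 and changed sign with the library left out, from -367 without MDA-MB-231 replicate 2 to 261 without MDA-MB-231 replicate 1. Most regions of the longer lists lay within 2 Mb of a centromere or heterochromatin gap of the assembly, where repeat sequence is abundant. Away from the gaps lay 208 of the 646 regions of MDA-MB-231 replicate 1 (32.2%, exact 95% interval 28.6 to 36.0%) and 117 of the 472 of MDA-LM2 replicate 2 (24.8%, 20.96 to 28.9%). In the shorter lists the share away from the gaps was higher, at 14 of 18 regions in MDA-MB-231 replicate 2 (77.8%, 52.4 to 93.6%) and 70 of 86 in MDA-LM2 replicate 1 (81.4%, 71.6 to 89.0%). Counting only these regions, the lines had 111 ± 137 and 93.5 ± 33.2 (SD, n = 2 each, exact permutation p = 1, smallest possible 0.333).

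**Figure D1:**
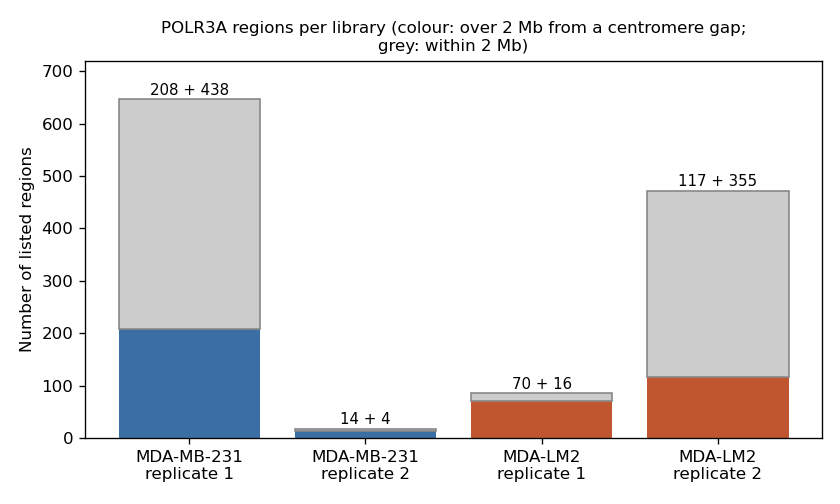
Number of listed POLR3A regions per ChIP library (vertical axis), with regions over 2 Mb from a centromere gap in colour (blue for MDA-MB-231, orange for MDA-LM2) and regions within 2 Mb in grey; the numbers above each bar give the former and then the latter. The replicates of a line differ more than the lines do, with 646 and 18 regions in MDA-MB-231 and 86 and 472 in MDA-LM2.

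A core of 10 regions was listed in all 4 libraries, and all 10 lay away from the centromere gaps. MDA-MB-231 replicate 2, the library with 18 regions, listed only 4 near the gaps, which limits how many of those the core could hold. Without this library, 51 were listed in every remaining library, 41 away from the gaps and 10 near them. The highest ranked of the core was on chromosome 19 at 1383104 to 1383785. It had strength scores of 26.4 and 15.6 in MDA-MB-231 replicates 1 and 2 and of 11.8 and 17.5 in MDA-LM2 replicates 1 and 2. On chromosome 1, the region at 161509772 to 161510431 had scores of 27.2, 13.8, 13.3 and 18.7 in the same order. A neighbouring region at 161499880 to 161501300 had 27.5, 11.7, 10.3 and 14.2, and another on that chromosome, at 145399002 to 145399607, had 24.6, 12.9, 10.9 and 15.5. The region on chromosome 17 at 37310442 to 37311023 had 25.8, 14.5, 11.2 and 17.7, and that on chromosome 9 at 35657492 to 35658210 had 20.0, 13.8, 11.1 and 16.5. Chromosome 5 held 3 of the 10, at 180615237 to 180616294, 180633612 to 180634168 and 140090498 to 140091227. The last was on chromosome 14 at 23398624 to 23399201. Scores are the authors' values and rank regions within a list only, so no score was compared between libraries.

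Regions held by 3 of the 4 libraries included strong signal beside centromeres. The merged region on chromosome 6 at 58776106 to 58780232 was listed in MDA-MB-231 replicate 1 and in both MDA-LM2 libraries. So were the regions on chromosome 17 at 22258970 to 22262255 and 22247685 to 22252394. On chromosome 1, the regions at 121485378 to 121485543 and 121483011 to 121484711 were listed in both MDA-MB-231 libraries and in MDA-LM2 replicate 2. In all, the 4 lists merged into 788 regions, of which 57 were held by at least 3 libraries and 495 by 1 library. Of the 57, 44 lay away from the gaps. Merged regions can join lists through a chain of overlaps, so the libraries counted need not all overlap directly.

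The same positions were listed in both lines far more often than random placement gave. Random placement did not avoid assembly gaps, so it cannot separate bound polymerase from repeat signal that recurs in several lists. Of the 18 regions of MDA-MB-231 replicate 2, 16 were found in MDA-MB-231 replicate 1 (88.9%, exact 95% interval 65.3 to 98.6%), 16 in MDA-LM2 replicate 2 and 10 in MDA-LM2 replicate 1. Of the 86 regions of MDA-LM2 replicate 1, 73 were found in MDA-MB-231 replicate 1 (84.9%, 75.5 to 91.7%) and 56 in its own replicate, MDA-LM2 replicate 2 (65.1%, 54.1 to 75.1%). Of the 472 regions of MDA-LM2 replicate 2, 314 were found in MDA-MB-231 replicate 1 (66.5%, 62.1 to 70.8%). Of these 314, 213 lay near the gaps. Away from the gaps, 59 of 70 regions of MDA-LM2 replicate 1 and 101 of 117 of MDA-LM2 replicate 2 were found in MDA-MB-231 replicate 1. Placed at random on their chromosomes, at most 0.25 regions on average overlapped in any pair, and every pair had the smallest possible permutation p of 0.001 (adjusted p = 0.001 over 6 pairs). Regions are clustered, and moved by only 5 to 50 kb the regions of MDA-LM2 replicate 2 overlapped MDA-MB-231 replicate 1 at 34.1 on average (highest 55), with at most 2.49 on average in the other pairs and the same permutation p of 0.001 in all 6. With the strongest 18 regions of each list, no region of MDA-LM2 replicate 1 was shared with MDA-LM2 replicate 2 (permutation p = 1). The reciprocal rule of 50% lowered the shared regions of all 6 pairs to between 3 and 109.

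No region was held by both MDA-MB-231 libraries and neither MDA-LM2 library, and 3 regions were held by both MDA-LM2 libraries and neither MDA-MB-231 library. These were on chromosome 10 at 42545929 to 42546124, on chromosome 1 at 249167801 to 249168269 and on chromosome 16 at 57333745 to 57334652. Their strength scores in MDA-LM2 replicates 1 and 2 were 13.1 and 18.1, 9.22 and 12.4, and 6.95 and 14.4. The chromosome 16 region had the lowest score of the whole MDA-LM2 replicate 1 list. Its highest positions were at 57333946 and 57334450 in MDA-LM2 replicates 1 and 2. The region on chromosome 10 lay near the centromere gap, 4.14 kb from a region of MDA-MB-231 replicate 1. Under the reciprocal overlap of 50% the counts were 1 and 14, and with the strongest 18 regions of each list they were 0 and 0. The 18 regions of MDA-MB-231 replicate 2 limit how many could be found in both libraries of that line: without this library, 331 merged regions were listed in MDA-MB-231 only. Without MDA-LM2 replicate 1, 157 were listed in MDA-LM2 only, against 43 without MDA-MB-231 replicate 1 and 13 without MDA-LM2 replicate 2.

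Of the 5 highest scores of each library, at least 4 lay within 2 Mb of a gap. Of the 10 highest, 1 and 6 lay away from the gaps in MDA-MB-231 replicates 1 and 2, and 4 and 0 in MDA-LM2 replicates 1 and 2. Over the whole list of MDA-MB-231 replicate 1, median scores near and away from the gaps were 16.84 and 17.02 (permutation p = 0.818, adjusted p = 0.818 over 8 tests). In the other lists, scores near the gaps were higher. Medians were 86.9 and 13.2 in MDA-MB-231 replicate 2, with only 4 regions near the gaps (permutation p = 0.0023, adjusted p = 0.0092). They were 10.97 and 9.09 in MDA-LM2 replicate 1 (permutation p = 0.0044, adjusted p = 0.0117). In MDA-LM2 replicate 2 they were 13.87 and 12.35 (permutation p = 0.0096, adjusted p = 0.0192). In MDA-MB-231 replicate 1 the 5 highest scores were 128 at chromosome 1 121484371 to 121484610, 115 at chromosome 7 61969416 to 61969704, 83.0 at chromosome 9 66971241 to 66971507, 81.6 at chromosome 19 27731979 to 27732255 and 79.4 at chromosome 18 109162 to 109399. The last was the only one over 2 Mb from a gap. In MDA-MB-231 replicate 2 they were 127 at chromosome 10 42597013 to 42597222, 87.0 at chromosome 1 121485378 to 121485543, 86.8 at chromosome 1 121483970 to 121484123, 48.2 at chromosome 10 42380192 to 42380302 and 15.6 for the chromosome 19 region of the core. In MDA-LM2 replicate 2 all 5 lay near gaps, with 107 at chromosome 1 121483956 to 121484711, 79.4 at chromosome 7 61968560 to 61970692, 66.6 at chromosome 10 42599516 to 42600400, 62.5 at chromosome 10 42388798 to 42389613 and 62.1 at chromosome 19 27731868 to 27732411. In MDA-LM2 replicate 1 the highest scores were 22.8 at chromosome 6 58779387 to 58779575, 17.1 at chromosome 17 22260271 to 22260455, 16.3 at chromosome 2 92317236 to 92317385 and 13.9 at chromosome 17 22248375 to 22248492. The next, with 13.3, was at chromosome 1 228745864 to 228746298, within the array described next.

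Away from the centromeres, regions gathered in clusters, some of which the libraries listed unequally. An array on chromosome 1 between 228.7 and 228.8 Mb held 15 regions in MDA-MB-231 replicate 1 and 15 in MDA-LM2 replicate 1, but 2 in MDA-LM2 replicate 2 and none in MDA-MB-231 replicate 2. In MDA-MB-231 replicate 1 the regions were evenly spaced, with a median of 2233 bp over 14 steps (2105 to 2344). In MDA-LM2 replicate 1 the 14 steps had a median of 2201 bp and ran from 345 to 4605 bp, with 10 of them between 1000 and 3500 bp. In the GRCh38.p14 gene table, all 17 genes of 5S rRNA, a ribosomal RNA made by RNA polymerase III, are on chromosome 1, and 16 of them neighbour one another when 5S pseudogenes are passed over. Of the 15 array regions of MDA-MB-231 replicate 1, 11 were found in MDA-LM2 replicate 1, against 42 of its 193 other regions away from the gaps (Fisher's exact p = 7.19e-05, adjusted p = 0.00129 over 18 tests). In MDA-LM2 replicate 2 the numbers were 2 of 15 against 99 of 193 (Fisher's exact p = 0.00582, adjusted p = 0.0347 over 18 tests). Array regions were among the weaker ones of MDA-MB-231 replicate 1, with a median percentile of 25.5, and with regions permuted within 5 classes of strength 2 found compared with 4.88 on average (two-sided permutation p = 0.136, adjusted p = 0.136 over 2 tests). Of the 15 array regions of MDA-LM2 replicate 1, with a median percentile of 77.1, 2 were found in MDA-LM2 replicate 2, against 41 of its 55 others and against 8.91 on average within classes of strength (permutation p = 0.0002, adjusted p = 0.0004 over 2 tests). These tests compare libraries, not lines, and the array was chosen for its many regions in these lists. They also treat neighbouring regions of the array as independent.

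A second large cluster lay on chromosome 6 between 26 and 29 Mb, with 43 regions in MDA-MB-231 replicate 1, 1 in MDA-MB-231 replicate 2, 3 in MDA-LM2 replicate 1 and 14 in MDA-LM2 replicate 2. Of the 43, 3 were found in MDA-LM2 replicate 1, against 50 of the 165 others (Fisher's exact p = 0.00137, adjusted p = 0.0124 over 18 tests), and 14 in MDA-LM2 replicate 2, against 87 of 165 (p = 0.0253, adjusted p = 0.0651). On chromosome 17 between 8 and 9 Mb, MDA-MB-231 replicate 1 listed 11 regions, MDA-LM2 replicate 1 listed 7 and MDA-LM2 replicate 2 listed 10. There, 4 and 8 of the 11 were found in MDA-LM2 replicates 1 and 2 (Fisher's exact adjusted p = 0.536 and 0.252 over 18 tests). On chromosome 5 between 180 and 181 Mb, 3 and 6 of the 6 regions of MDA-MB-231 replicate 1 were found in MDA-LM2 replicates 1 and 2 (Fisher's exact adjusted p = 0.314 and 0.0364 over 18 tests). The clusters on chromosome 1 at 0 to 1 and 161 to 162 Mb, chromosome 14 at 21 to 22 Mb and chromosome 17 at 37 to 38 Mb passed adjusted p 0.05 in neither list. Clusters were picked by region counts over the 4 lists, and MDA-MB-231 replicate 1 gave most regions of the chromosome 6 cluster. A low share found elsewhere may come from that choice, and the tests treat neighbouring regions as independent.

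**Figure D2:**
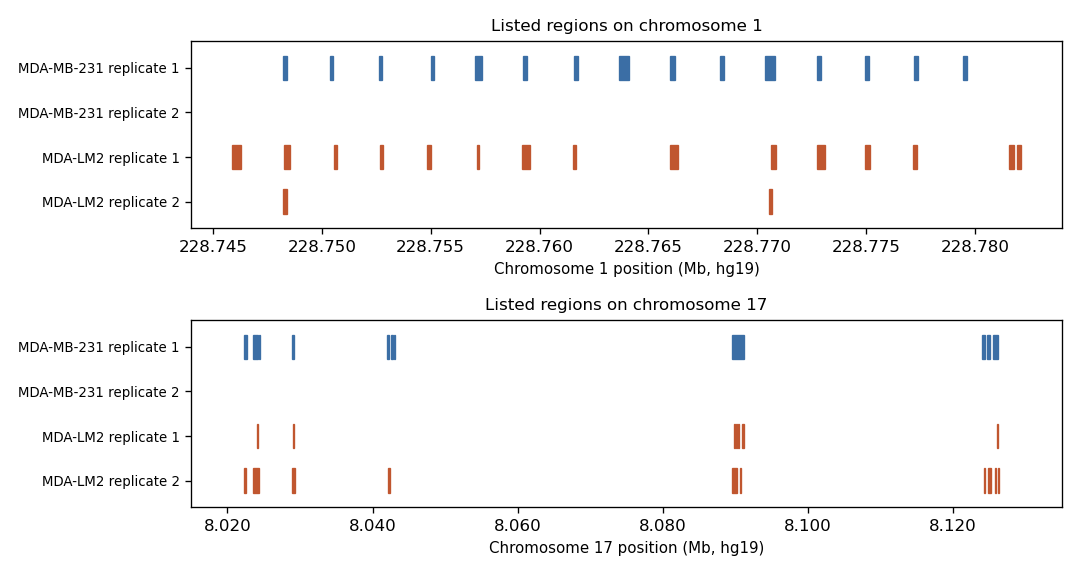
Listed regions along the chromosome 1 array (top) and a cluster on chromosome 17 (bottom), with hg19 position in Mb on the horizontal axis and 1 line of boxes per ChIP library, drawn to scale in blue for MDA-MB-231 and orange for MDA-LM2. The array holds 15, 0, 15 and 2 regions in the order of the lines from top to bottom, while the chromosome 17 cluster is listed in both MDA-LM2 libraries.

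Chromosomes with more tRNA genes held more regions away from the centromere gaps. Of 443 nuclear tRNA genes in the GRCh38.p14 table, chromosome 6 holds 155, chromosome 1 holds 98 and chromosome 17 holds 33. On these chromosomes MDA-MB-231 replicate 1 listed 46, 43 and 23 regions away from the gaps, and MDA-LM2 replicate 2 listed 16, 19 and 20. Across 24 chromosomes, Spearman's rho was 0.83 in MDA-MB-231 replicate 1 (permutation p = 1e-05, the smallest possible, adjusted p = 4e-05 over 8 correlations) and 0.81 in MDA-LM2 replicate 2 (p = 1e-05, adjusted p = 4e-05). It was 0.76 in MDA-LM2 replicate 1 (permutation p = 5e-05, adjusted p = 0.00013) and 0.57 in MDA-MB-231 replicate 2 (permutation p = 0.0045, adjusted p = 0.0091). Pearson's r was 0.90 in MDA-MB-231 replicate 1 (permutation p = 1e-05, adjusted p = 8e-05) and 0.76 in MDA-LM2 replicate 2 (p = 0.001, adjusted p = 0.0041). In MDA-MB-231 replicate 2 and MDA-LM2 replicate 1 it was 0.50 and 0.54 (permutation p = 0.038 and 0.043, adjusted p = 0.087 for both). Without chromosomes 1 and 6, r was 0.61, 0.44, 0.72 and 0.77 in MDA-MB-231 replicates 1 and 2 and MDA-LM2 replicates 1 and 2.

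Regions near the gaps showed no such relation in the 2 long lists. There, rho was -0.018 in MDA-MB-231 replicate 1 and 0.14 in MDA-LM2 replicate 2 (permutation p = 0.93 and 0.52, adjusted p = 0.93 and 0.65 over 8 correlations). For these regions r was -0.12 and -0.079 (permutation p = 0.55 and 0.76, adjusted p = 0.63 and 0.76), and -0.21 and 0.082 without chromosomes 1 and 6. In MDA-LM2 replicate 1 rho was 0.42 and r 0.20 (permutation p = 0.044 and 0.092, adjusted p = 0.071 and 0.15), with r 0.56 without chromosomes 1 and 6. In MDA-MB-231 replicate 2 they were 0.13 and 0.28 (permutation p = 0.57 and 0.14, adjusted p = 0.65 and 0.18), with r -0.13 without these chromosomes. Chromosome 4, with 1 tRNA gene, held 103 near-gap regions in MDA-MB-231 replicate 1 and 30 in MDA-LM2 replicate 2. These correlations are across chromosomes within 1 library, chromosomes also differ in length, and the gene counts come from another assembly than the regions. The gene counts also cover whole chromosomes, near and away from the gaps together.

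**Figure D3:**
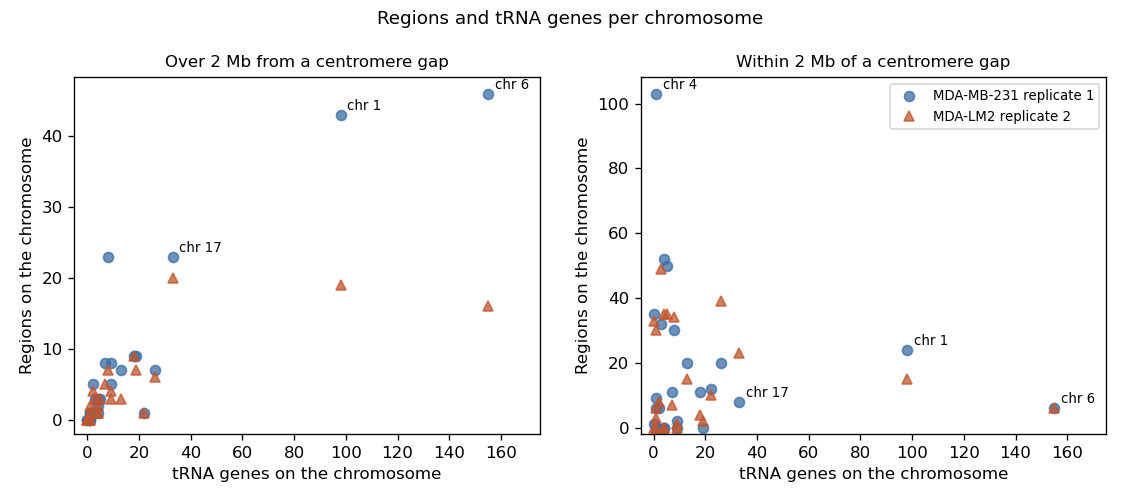
Number of tRNA genes per chromosome in the GRCh38.p14 gene table (horizontal axis) against the number of hg19 POLR3A regions on that chromosome (vertical axis), away from the centromere gaps (left) and near them (right). Each point is 1 of 24 chromosomes, blue circles for MDA-MB-231 replicate 1 and orange triangles for MDA-LM2 replicate 2, and chromosomes 6 and 1 stand highest in MDA-MB-231 replicate 1 on the left, with 46 and 43 regions.

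In the longer list of each pair, regions away from the gaps that the shorter list shared were the stronger ones. Those of MDA-MB-231 replicate 1 found in MDA-MB-231 replicate 2 had a median score percentile of 88.0, against 47.1 for the others (one-sided permutation p = 0.0002, adjusted p = 0.0006 over 6 comparisons). Those found in MDA-LM2 replicate 2 had 65.4 against 33.2, and those found in MDA-LM2 replicate 1 had 67.3 against 44.7 (one-sided permutation p = 0.0001, the smallest possible, and 0.0016, adjusted p = 0.0006 and 0.0024). In MDA-LM2 replicate 2, regions found in MDA-LM2 replicate 1 had 70.1 against 40.2 (one-sided permutation p = 0.0003, adjusted p = 0.0006). Some of the strongest regions over 2 Mb from a gap lay close to chromosome ends. Examples chosen after their values were seen are 3 of MDA-MB-231 replicate 1, with scores of 79.4 on chromosome 18 at 109162 to 109399 and of 42.7 and 37.7 on chromosome 1 at 569326 to 569561 and 564911 to 565498. Those on chromosome 1 lay beside each other, so they are not separate examples. No input library was used here, so whether any of these strong regions reflect bound polymerase was not tested.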

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

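The alternatives restricted to regions away from the gaps, those with other gap distances, the placements 5 to 50 kb away, the counts over every library, the distance of 500 bp for array regions, their permutation within classes of strength and all alternatives to the difference between the lines in regions per library were chosen after the results were seen, and the others were planned. Of 89 alternative values, 54 stayed within 1.5 times the main count (1 SD for the difference between the lines), 33 moved further and 2 no longer passed their test. One of these was the 2 array regions of MDA-MB-231 replicate 1 found in MDA-LM2 replicate 2, with a permutation p of 0.136 within classes of strength, and the other was MDA-LM2 replicate 1 in replicate 2 with the strongest 18 regions. The difference between the lines, which passed no test, changed sign in 4 of the values with a library left out. Keeping the strongest 50% of each list left 323, 9, 43 and 236 regions by construction, in MDA-MB-231 replicates 1 and 2 and MDA-LM2 replicates 1 and 2. It left 7 shared regions for MDA-MB-231 replicate 2 in replicate 1, 26 and 144 for MDA-LM2 replicates 1 and 2 in MDA-MB-231 replicate 1, 4 and 8 for MDA-MB-231 replicate 2 in MDA-LM2 replicates 1 and 2, and 23 for MDA-LM2 replicate 1 in replicate 2. In the same order the reciprocal overlap of 50% left 4, 13, 109, 5, 3 and 22 shared regions, and the strongest 18 regions left 2, 1, 8, 4, 3 and 0. MDA-LM2 replicate 1 in replicate 2 then had a permutation p of 1, and the other alternatives with a placement test kept the smallest possible permutation p of 0.001. Away from the gaps, 101 of 117 regions of MDA-LM2 replicate 2 were in MDA-MB-231 replicate 1, fewer by construction. The regions found in MDA-MB-231 only rose from 0 to 1 with the reciprocal rule, counted on the regions of replicate 1, and ranged from 1 to 331 with 1 library left out. They were 331 without MDA-MB-231 replicate 2, 5 without MDA-LM2 replicate 2 and 1 without either other library. Those in MDA-LM2 only went from 3 to 14 with the reciprocal rule and 0 with the strongest 18, and ranged from 3 to 157. They were 157 without MDA-LM2 replicate 1, 43 without MDA-MB-231 replicate 1, 13 without MDA-LM2 replicate 2 and 3 without MDA-MB-231 replicate 2. Regions held by every library ranged from 10 to 51, with 51 without MDA-MB-231 replicate 2. Leaving out a library removes a condition and so changes these counts by construction, and for the reciprocal rule the cause was not tested. The distance of 500 bp, and gap distances of 1 and 5 Mb, moved no count by over 1.5 times. With the replicate number as a block, the difference between the lines of -53 regions (pairs of -560 and 454) had an exact sign-flip p of 1, where 2 pairs allow no value below 0.5, and that of -17.5 regions away from the gaps also had 1; crossed numbers gave the same p. The labels do not say that the numbers pair the libraries. With 1 library left out these differences ranged from -367 to 261 and from -114.5 to 79.5. For the shared and line-only regions, no paired analysis was run, since they are counts from lists without a value per library for a common set of features. Alternatives set before the data were examined for RNA polymerase III genes, anticodons, promoters and differential occupancy were not run, since those results need an annotation or common features not used here. Depth is unknown, so a region missing from a short list cannot be called unbound.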

Other observations

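All tests of this part were chosen after the results were seen. The cluster on chromosome 6 between 26 and 29 Mb held weaker regions of MDA-MB-231 replicate 1, with a median percentile of 39.4 among its regions away from the gaps. With regions permuted within 5 classes of strength, 3 of its 43 regions found in MDA-LM2 replicate 1 compared with 9.62 on average (two-sided permutation p = 0.0068, adjusted p = 0.0136 over 2 tests). In MDA-LM2 replicate 2 it was 14 against 18.6 (permutation p = 0.114, adjusted p = 0.114). A cluster on chromosome 2 between 89 and 90 Mb held 17 regions in MDA-MB-231 replicate 1, 3 in MDA-LM2 replicate 2 and none in the other libraries, although its median percentile was 76.0. It lay within 5 Mb of the chromosome 2 gap, so at that alternative distance it would count as near a gap. Both it and the chromosome 6 cluster were picked by region counts over the 4 lists, most from MDA-MB-231 replicate 1. Their tests treat neighbouring regions as independent. Of the 17, 0 were found in MDA-LM2 replicate 1, against 53 of 191 others (Fisher's exact p = 0.00771, adjusted p = 0.0347 over 18 tests), and 3 in MDA-LM2 replicate 2, against 98 of 191 (Fisher's exact p = 0.00998, adjusted p = 0.0359). On chromosome 14 between 21 and 22 Mb, the same lists held 6 and 4 regions, and MDA-LM2 replicate 1 held 1.

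At 1 bp of overlap, MDA-LM2 replicate 1 shared more regions with MDA-MB-231 replicate 1 than with its own replicate, and the reciprocal overlap of 50% turned the direction, with 13 and 22 of 86 regions. Of its 86 regions, 21 were in MDA-MB-231 replicate 1 and not in MDA-LM2 replicate 2, and 4 the other way round (exact McNemar test, p = 0.000911). Outside the chromosome 1 array the numbers were 12 and 4 of 71 regions (exact McNemar p = 0.0768). With the strongest 50% of each list the counts were 26 and 23 of 43. These tests compare lists of different lengths. Summits of regions shared 1 to 1 away from the gaps lay a median of 38 bp apart between MDA-MB-231 replicate 1 and MDA-LM2 replicate 1 (49 regions) and 59 bp apart between the MDA-LM2 replicates (41 regions). Near the gaps the order was reversed, with 122 bp (7 regions) and 74 bp (9 regions).

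The replicates of a line differed widely in list length, and regions near the centromere gaps gave most of the difference in MDA-MB-231 (438 against 4) and in MDA-LM2 (355 against 16). Signal near the centromere gaps was not the whole cause in MDA-MB-231, since away from the gaps the ratio of the lists was still 14.9 (exact 95% interval 8.66 to 27.7, against 35.9 for all regions). In MDA-LM2 the ratio away from the gaps was 1.67 (1.23 to 2.28, against 5.49). There too the longer list stayed longer away from the gaps, beyond counting error. Whether the MDA-LM2 lists differ by over 1.5 times without such regions stays open, and this limit was set after the data were seen. A lower sensitivity of the shorter list stays open: the regions it kept had a median percentile of 88.0 in the longer MDA-MB-231 list and 70.1 in the longer MDA-LM2 list (one-sided permutation p = 0.0002 and 0.0003), but shared regions were the stronger ones in all 6 pairs, those across lines included, so this does not separate it from other causes. Read totals were not used here, and no biological explanation was tested, because the replicates of a line have the same labels.

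The chromosome 1 array was listed in MDA-MB-231 replicate 1 and MDA-LM2 replicate 1 and nearly absent from MDA-LM2 replicate 2. A generally lower sensitivity of that list stays open. Of the array regions of MDA-LM2 replicate 1, 2 were found there against 8.91 on average within classes of strength (adjusted permutation p = 0.0004). Those of MDA-MB-231 replicate 1 ranked lower in their own list (2 against 4.88, adjusted permutation p = 0.136). The array was chosen for its many regions, these included, and its neighbouring regions were permuted as if independent. The low p therefore cannot decide about the list of MDA-LM2 replicate 2. A higher pile-up needed at the array remains open, because its lowest listed height there was 20, above the lower quartile of 14 over its regions away from the gaps, while heights of array copies that it did not list were not used here. As a hypothesis from the even spacing in MDA-MB-231 replicate 1 and from the neighbouring 5S rRNA genes of chromosome 1, the array may be the 5S rRNA genes, which an hg19 annotation would decide. No biological explanation was tested, since the MDA-LM2 replicates have the same labels.

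Regions near the centromere gaps were many in MDA-MB-231 replicate 1 and MDA-LM2 replicate 2. Across chromosomes, their number showed no relation to that of tRNA genes in MDA-MB-231 replicate 1. There, rho was -0.0184, against 0.83 for its regions away from the gaps. The gene counts cover whole chromosomes, so this cannot decide whether regions near the gaps lie at tRNA genes. Repeat reads assigned to copies in the assembly from which they did not come may account for the regions near the gaps. All 68 regions listed on chromosome Y, 35 in MDA-MB-231 replicate 1 and 33 in MDA-LM2 replicate 2, lay near a gap. Reads would decide and were not used here, so misassigned reads cannot be told apart from polymerase bound at these repeats. Each library listed some regions near the gaps, though MDA-MB-231 replicate 2 listed only 4, and 0 of them were in all 4 libraries. The number of regions near the gaps did not differ between the lines beyond the replicate spread (221 ± 307 and 185.5 ± 240, SD, n = 2 each, exact permutation p = 1, smallest possible 0.333).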
